A study of Oryza sativa Indica Group with 6 samples.

How the data were processed

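RNA of the rice male gametophyte was measured in 6 samples, 2 biological replicates of uninucleate microspores (UNM), of bicellular pollen (BCP) and of tricellular pollen (TCP). Plants of the variety Guichao No.2 were grown in the field, and biotin-labelled cRNA was made from 5 ug of total RNA by the standard Affymetrix protocol, per the labels' protocols. The deposited values are on the log2 scale, 1 per probe set and array, and were made by the authors with RMA, per the submitters' processing notes. The version of RMA, the probe definitions and which arrays were normalised together are not given in the sources used here. The values were used as deposited, and their range of about 2 to 14 on every array was checked.

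The table held 57381 probe sets. The 123 Affymetrix control and 64 reporter probe sets, 187 in all, were left out of the tests and used as controls, and 57194 were tested. The annotation given with the platform named genes for 22531 probe sets, of which 22436 had 1 gene and 95 had several. The other 34663 tested probe sets are unnamed here. The 17905 genes with a probe set were all found by gene ID in the RefSeq gene table, of which no coordinates were used, and 2457 of them had a name beyond a locus or clone number. These tables gave names and no descriptions. No genome build is named for the array, so no positions are given.

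Stages were compared with limma 3.58.1 in R 4.3.3, in a single linear fit of the 6 arrays with stage as the factor and empirical Bayes moderation without trend or robust prior (residual degrees of freedom 3, prior 3.87). The median standard error of a difference was 0.156. A probe set rose or fell where the Benjamini-Hochberg adjusted p was under 0.05 and the difference was at least 1 on the log2 scale. The moderated F test of the same fit, with the same threshold and a range of the stage means of at least 1, gave the probe sets that changed across the 3 stages. Where 2 stage means were equal, the earlier stage was counted as the higher. All tests were two-sided. Every comparison rests on 2 arrays per stage, and comparisons that share a stage are not independent of each other. A gene measured by several probe sets was represented by the one with the highest mean over all arrays. Of 337 results of named genes that passed, counted once per probe set and comparison, 46 came from probe sets shared by several transcripts. Other probe sets of the gene were measured for 70, of which all gave the same call for 14, some for 11 and none for 45, and an opposite call was given for 4.

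Gene lists were compared by counts and by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists and comparisons. An estimated correlation, with which 0 lists were called by camera although 3, 2 and 1 of the called lists of the 3 comparisons had an unadjusted p under 0.05, and fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes, were the alternatives. With an estimated correlation camera has only the 3 residual degrees of freedom, and thus little power after adjustment over lists. For ribosomal proteins from BCP to TCP its unadjusted p was 0.00836, against 1.54e-08 with the preset correlation. The 0 calls therefore cannot decide whether correlation among genes accounts for a call. Of 28 lists fixed beforehand by names and descriptions 9 had a match, because the tables hold no descriptions. A further 27 lists by symbol family were written after the tables had been seen and before their genes were tested. The proteasome list is an exception: its pattern also matched 3 ribophorin genes, and these were removed after the list had been tested. With them, 16 of 19 genes fell from BCP to TCP and 17 of 19 from UNM to TCP, with medians of -1.65 and -2.49 and unadjusted p of 2.67e-06 and 3.16e-05 by camera, against 4.15e-05 and 0.000163 without them.

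The named genes are the 8 largest rises and the 8 largest falls per comparison, among genes with a name whose probe set passed and had both arrays of a stage beyond both of the other, and up to 3 passing members per list. Members of the anther-wall and meiosis lists are named whether or not they passed. The stages, tests, thresholds, the rule for named genes, the lists fixed beforehand and the alternatives were chosen before the data were examined, except the scaling by hybridization controls, the added lists and the condition on names. The rule asked for genes with an informative description, and a name beyond a locus or clone number was taken instead once the tables were found to hold no descriptions. The alternatives were quantile normalisation of the 6 arrays again, centring on the median or on the 75th percentile, leaving out dim probe sets, leaving out probe sets shared by several transcripts, 1 probe set per gene, an intensity trend, a robust prior, no minimum difference, a minimum of 2, a replicate block, only the 2 stages compared, and leaving out each array in turn. Scaling by the hybridization controls shifted each array so that the mean of its 21 bioB, bioC and bioD probe sets was equal.

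The fit and camera were tested on simulated data for TCP compared with UNM. Over 57194 probe sets, an adjusted p under the threshold was found for 79.1% of 67 probe sets changed by 1 on the log2 scale, 98.5% of 67 changed by 2 and 100% of 66 changed by 4, and for 11 of 56994 unchanged ones. Both criteria were met by 35, 66 and 66 of these changed probe sets and by 4 unchanged ones. Camera called 1 of 1 shifted list of 20 genes and 0 of 19 unshifted lists. The simulated noise was independent between probe sets and nearly all probe sets were unchanged, whereas 29.9% changed in the data from UNM to TCP. The simulation therefore does not show how camera performs with correlated genes or widespread change. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.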

Results

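Transcript levels were measured in the male gametophyte of rice (Oryza sativa Indica Group, variety Guichao No.2) at 3 stages of its development. Uninucleate microspores (UNM) still hold a single nucleus, bicellular pollen (BCP) holds a vegetative and a generative cell, and in tricellular pollen (TCP) the generative cell has divided into sperm cells. Each stage had 2 biological replicates, each on its own Affymetrix array, so that 6 arrays were compared. Values are signals on the log2 scale per probe set, a group of probes for 1 transcript. Levels are given as mean ± SD with n = 2 arrays per stage, and differences between stages as log2 differences with their standard error (SE). A total of 57194 probe sets were tested, of which 22436 were paired with 1 gene in the annotation. The p-values measure the spread between these samples, whose replicates the labels call biological. As with any arrays, their number limits the precision.

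The median signal was between 4.57 and 4.73 on the 6 arrays. The 64 probe sets for reporter genes of laboratory use, taken as background, had a 95th percentile between 5.00 and 5.84. The share of tested probe sets above that level was 38.6% and 42.3% on the UNM arrays, 31.7% and 30.4% on the BCP arrays and 29.6% and 27.8% on the TCP arrays. Across probe sets, which are not independent replicates, replicate arrays had a Pearson's r between 0.985 and 0.993. Between stages r was 0.826 to 0.827 for UNM and BCP, 0.835 to 0.841 for BCP and TCP, and 0.661 to 0.669 for UNM and TCP. Of the 48 largest rises and falls named in the 3 comparisons, 46 had their lower stage mean under the reporters' 95th percentile of that stage, all but MT2C and KIN7J. Background limits the size of those differences, so neither their size nor their order is exact. Another probe set of the gene was measured for 7 of the 48, and in 3 of these, PHT1-7, NifU1 and OsTrx20, no other probe set gave the same call. The probe sets of GBSS-I, RPL9 and NifU1 are shared with other transcripts.

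The comparison of BCP with UNM addressed how transcripts changed as the microspore became pollen with a vegetative and a generative cell. A starch synthase, 2 expansins and an actin regulator stood among the 8 largest rises. The largest rises and falls, here and below, were ranked only among the 2457 of 17905 genes with a name. BGLU38, a beta-glucosidase (gene 4352082), rose from 3.23 ± 0.08 to 12.59 ± 0.46, and the transporter gene YSL4 (gene 4338224) from 2.96 ± 0.01 to 11.90 ± 0.01. GBSS-I (gene 4340018), the granule-bound enzyme that makes amylose, rose from 3.52 ± 0.12 to 12.22 ± 0.00, and the beta-expansin gene EXPB9 (gene 4349301), of a family of cell-wall-loosening proteins, from 4.24 ± 0.46 to 12.90 ± 0.03. The largest falls were those of BIP4 (gene 4338866), of a family of chaperones of the endoplasmic reticulum, from 11.51 ± 0.14 to 3.83 ± 0.31, and of the lipid transfer protein gene LTP110-A (gene 4349601), from 9.58 ± 0.10 to 2.73 ± 0.01.

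By limma with Benjamini-Hochberg adjustment, adjusted p was 2.58e-07 for BGLU38, 1.29e-07 for GBSS-I and 5.83e-07 for BIP4. The other large rises were ADF-9, an actin-depolymerizing factor (8.19, SE 0.17), EXPB10 (7.59, SE 0.17), the cytochrome P450 gene CYP88A5 (7.55, SE 0.12) and CPK2, a calcium-dependent protein kinase (7.05, SE 0.13). The other large falls were CAB2R, a chlorophyll-binding protein of photosynthesis (-6.80, SE 0.13), C6 (-6.73, SE 0.31), JAZ13, of the repressors of jasmonate signalling (-6.72, SE 0.15), the aquaporin gene PIP2-6 (-6.63, SE 0.28), the glutamate dehydrogenase gene GDH3 (-6.48, SE 0.22) and the metallothionein gene MT2C (-6.39, SE 0.14). In total 12330 probe sets changed, of which 5300 rose and 7030 fell, so that rises made up 43.0%. Rises made up 49.8% after centring on the 75th percentile (6155 rose and 6198 fell). They made up 33.0% after scaling by the hybridization controls (4298 rose and 8710 fell). Changes of more than 4 on the log2 scale were found in 593 rises and 669 falls. With 1 probe set per gene, 3068 genes rose and 4502 fell of 17905.

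Of the 11 measured marker genes of the anther wall, whose inner layer, the tapetum, feeds the microspores and makes the outer pollen wall, 8 fell and 0 rose. C6 and C4, lipid transfer proteins of the tapetum, had levels of 10.82 ± 0.03 and 10.65 ± 0.06 in UNM and of 4.09 ± 0.22 and 4.32 ± 0.10 in BCP. The falls included CP1, a cysteine protease (-5.31, SE 0.19), CYP703A3, a cytochrome P450 of pollen wall synthesis (-5.27, SE 0.13), and AP25, an aspartic protease (-5.20, SE 0.41). The regulators of tapetum development TDR, EAT1 and BHLH142 fell, with differences of -2.40, -2.20 and -2.06. GAMYB had a difference of -0.81, OsRAFTIN1 of -0.61 and PTC1 of -0.43, none of which passed both criteria. The list's median difference was -2.40, with a Benjamini-Hochberg adjusted p of 0.00315 by camera, and adjusted p = 0.630 with an estimated correlation. Beside this list, 4 of 12 photosynthesis genes fell and 0 rose, and the ribosomal RNA probe sets differed by -3.25 (25S) and -1.90 (18S). The difference between the 3' and the middle probe set of control genes, a sign of RNA quality, moved from 3.10 in UNM to 1.87 in BCP for actin, a change of -1.23, and by -0.36 for GAPDH.

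Genes of DNA replication fell in the same comparison, with 17 of 30 falling and 1 rising. The falls included PCNA, the sliding clamp of DNA polymerases (-3.12, SE 0.13), and MCM5 and MCM4, of the replicative helicase (-2.61, SE 0.14 and -2.50, SE 0.14). The list's median difference was -1.17 with an adjusted p of 0.0412 by camera, against adjusted p = 0.634 with an estimated correlation, 0.0565 without UNM replicate 2 and 0.125 after scaling by the hybridization controls, when the median was -1.43 and 20 genes fell. Of 21 cell cycle genes 3 rose and 7 fell, and the rises included the cyclin genes CYCB2 (2.77, SE 0.20) and CYCA2-1 (2.65, SE 0.19). This list also holds MCM4 and MCM5, so that their falls count in both lists. The name CYCB2 is carried by different genes of the list. Of 32 kinesin genes, which encode motors on microtubules, 11 rose and 4 fell, or 10 and 8 after scaling by the hybridization controls. The rises included KIN14E (3.27, SE 0.16) and KIN12E (2.13, SE 0.19), while KIN14I fell by 2.86 (SE 0.15). Of 9 tubulin genes 3 rose and 3 fell, or 1 and 3 after that scaling, with OsTUB8 at 2.76 (SE 0.13) and TUB1 at -1.96 (SE 0.13).

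Among genes of hormone response, 24 of 57 auxin genes fell and 2 rose, and 25 fell and 2 rose when adjusted over the list alone. ARF13 and IAA17, of the transcription factors and repressors of the auxin response, had differences of -5.01 (SE 0.20) and -3.97 (SE 0.15), whereas OsGH3-5, of a family of enzymes that conjugate hormones with amino acids, rose by 3.83 (SE 0.15). The list's median difference was -0.92 with an adjusted p of 0.00416 by camera, against adjusted p = 0.630 with an estimated correlation. Of 7 autophagy genes 6 fell and 0 rose, with APG8D at -2.90 (SE 0.34), APG4A at -2.68 (SE 0.15) and APG4B at -2.13 (SE 0.14). Their median difference was -2.03 with an adjusted p of 0.0321 by camera, against adjusted p = 0.634 with an estimated correlation and 0.0936 after scaling by the hybridization controls, when the median was -2.30 and all 7 fell. Of 17 JAZ and TIFY genes 3 rose and 5 fell, and beside JAZ13 the genes JAZ7 and JAZ11 fell, with differences of -4.68 (SE 0.14) and -4.25 (SE 0.16).

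Of 7 starch synthesis genes 4 rose and 1 fell. Beside GBSS-I, AGPS2, a subunit of ADP-glucose pyrophosphorylase, rose from 5.68 ± 0.06 to 11.42 ± 0.05, and the starch synthase gene SSI from 6.22 ± 0.15 to 11.19 ± 0.03. Of 12 sugar transporter genes of the list fixed beforehand 1 rose and 5 fell, with SWEET11 at -5.70 (SE 0.16) and SWEET15 at -3.52 (SE 0.33). Of 25 further genes of sucrose and hexose use 9 rose and 6 fell. The monosaccharide transporter gene MST5 rose by 6.73 (SE 0.22), and the sucrose transporter gene OsSUT5 and the sucrose synthase gene OsSUS2 fell, with differences of -4.27 (SE 0.16) and -4.05 (SE 0.14). Of 20 genes of glycolysis and fermentation 6 rose and 4 fell, and the aldolase genes FBA2 and FBA3 differed by 6.23 (SE 0.13) and -3.52 (SE 0.15). Of 23 aquaporin genes 2 rose and 8 fell, with OsPIP1;2 at -5.72 (SE 0.16). Camera gave none of these lists an adjusted p under the threshold, and over the 32 lists not called in this comparison the values ran from 0.0682 to 0.974.

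Of 4 genes of the actin list, of which 2 are villins, a family of actin-bundling proteins, 3 rose and 1 fell. The rises were actin-6, also named ARP8, actin and Villin-2, at 3.82 (SE 0.14), 2.10 (SE 0.12) and 2.73 (SE 0.13), and actin reached 13.71 ± 0.03 in BCP. Of 27 genes of the added list of actin regulators 8 rose and 8 fell, with ADF1 at 6.28 (SE 0.20) and VLN4 at 5.82 (SE 0.12). The added list also holds actin, Villin-2 and Villin-5 of the actin list. Of 77 calcium sensors and calcium-dependent kinases 22 rose and 22 fell, or 19 and 25 after scaling by the hybridization controls, and the calmodulin-like genes CML32 and CML28 rose by 5.68 (SE 0.16) and 5.61 (SE 0.17). Of 7 small GTPases of the Rac family 1 rose and 2 fell, and OsRac6 rose from 9.17 ± 0.28 to 13.15 ± 0.04. Of 29 expansin genes 4 rose and 11 fell, with EXPB4 at -5.00 (SE 0.19). Of 29 cellulose synthase and related genes 6 rose and 9 fell, and CESA6 fell by 4.62 (SE 0.16).

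Of 31 MADS box genes, transcription factors of flower development, 4 rose and 12 fell, with MADS45 at -3.36 (SE 0.27), MADS16 at -2.95 (SE 0.12) and MADS1 at -2.81 (SE 0.24). Of 6 WRKY genes 1 rose and 3 fell. Of 24 heat shock genes 0 rose and 6 fell, with hsp101 at -2.84 (SE 0.20) and HSP17.9B at -2.76 (SE 0.15). Of the 6 genes matched by the vesicle traffic list 1 rose and 1 fell, and these were RAB16D (1.63, SE 0.20) and rab25 (-2.56, SE 0.19), which encode dehydrins and not traffic proteins. Of 9 meiosis genes 4 rose and 1 fell, or 3 and 3 after scaling by the hybridization controls, with SPO11-4 at 1.91 (SE 0.17) and SPO11-3 at 1.68 (SE 0.18), of the family of topoisomerase-like proteins that includes the meiotic DNA-cleaving enzyme. For the lists of anther wall, cell cycle, sugar transport, actin, heat shock, MADS box, WRKY, vesicle traffic and meiosis genes, which were fixed beforehand, the counts adjusted over the list alone were equal to those over all probe sets in all 3 comparisons. From UNM to BCP, scaling by the hybridization controls or centring on the 75th percentile moved the number of rises or of falls by at most 6 in each of the 36 lists.

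**Figure D1:**
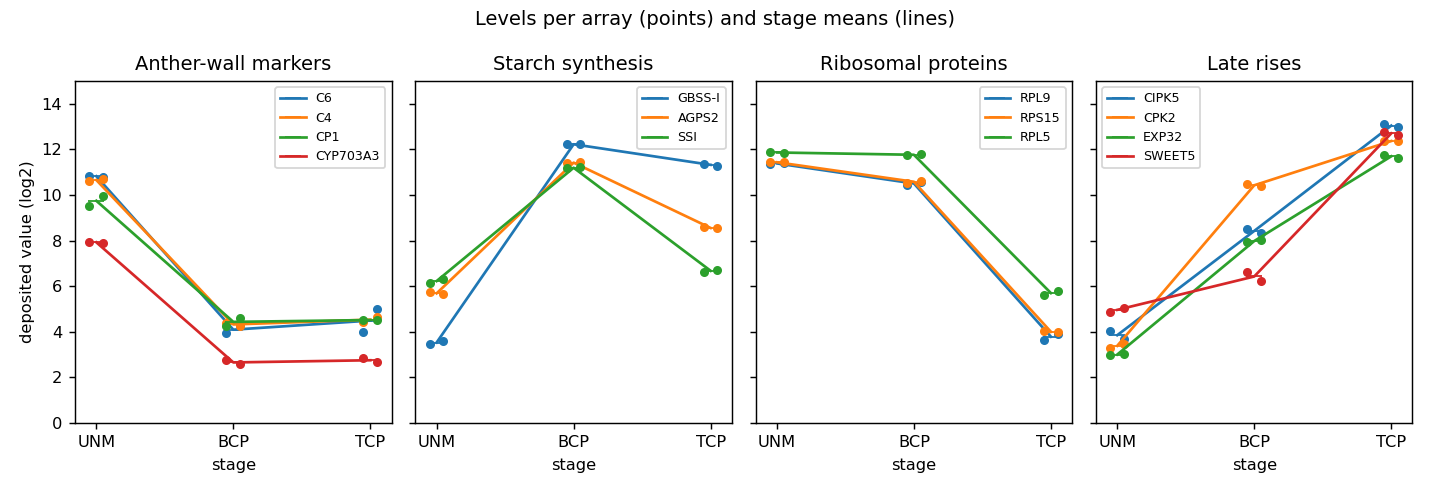
Deposited values on the log2 scale (vertical axis) at the 3 stages (horizontal axis) for 4 anther-wall markers, 3 genes of starch synthesis, 3 of ribosomal proteins and 4 genes higher in TCP than in UNM, with a point per array (n = 2 per stage) and lines through the stage means. The heading late rises stands over these last genes, although part of their rise came from UNM to BCP. GBSS-I rose from 3.52 in UNM to 12.22 in BCP, RPL9 fell from 10.50 in BCP to 3.78 in TCP, and CIPK5 rose from 8.42 in BCP to 13.04 in TCP.

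The comparison of TCP with BCP addressed the changes during the formation of sperm cells and the maturation of pollen. Of the genes of ribosomal proteins 20 of 22 fell, of proteasome subunits 13 of 16 and of protein folding in the endoplasmic reticulum 11 of 17. Camera called these 3 lists with the preset correlation and 0 of them with an estimated one, which has little power here. The 8 largest rises among genes with a name included genes of transporters, a kinase and a kinesin. RPL9 (gene 4347422) and RPS15 (gene 4342580), of the large and the small ribosomal subunit, fell from 10.50 ± 0.11 to 3.78 ± 0.19 and from 10.58 ± 0.07 to 3.99 ± 0.02. ASA1 (gene 4334640), an anthranilate synthase subunit of tryptophan synthesis, fell by 7.42 (SE 0.16) to 4.58 ± 0.18. SPPL3 (gene 4324348), a signal peptide peptidase-like gene, rose from 3.92 ± 0.21 to 11.76 ± 0.02, and NEK3 (gene 4342542), of the NIMA-related kinases, from 3.97 ± 0.22 to 11.49 ± 0.04.

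By limma with Benjamini-Hochberg adjustment, adjusted p was 4.52e-07 for RPL9 and ASA1 and 4.29e-07 for SPPL3. The other large rises were SIP2-1, of the aquaporin family (7.32, SE 0.17), the transcription factor gene BZIP02 (7.28, SE 0.16), the potassium transporter gene HAK20 (6.81, SE 0.16), the kinesin gene KIN7J (6.70, SE 0.14), the phosphoenolpyruvate transporter gene PPT2 (6.70, SE 0.18) and YSL1 (6.47, SE 0.13). The other large falls were the phosphate transporter gene PHT1-7 (-6.72, SE 0.13), RPN-II, a ribophorin of the enzyme that glycosylates proteins in the endoplasmic reticulum (-6.58, SE 0.14), DAPDC, of lysine synthesis (-6.56, SE 0.14), the zinc finger gene OsC3H54 (-6.47, SE 0.17) and the translation elongation factor gene EF-1-beta (-6.33, SE 0.20). In total 10992 probe sets changed, of which 3399 rose and 7593 fell, so that rises made up 30.9%. Without a minimum difference 11436 rose and 10331 fell, and rises made up 52.5%. Changes of more than 4 on the log2 scale were found in 348 rises and 681 falls. With 1 probe set per gene, 1526 genes rose and 5120 fell.

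This split depended on the scaling between arrays. The mean of the 21 hybridization control probe sets, which detect labelled bacterial transcripts added before hybridization, was 1.23 higher in TCP than in BCP, and 19 of the 21 passed both criteria. After scaling by them, 921 probe sets rose and 33406 fell, so that rises made up 2.68%. The 6 control probe sets for cre, which were not used for this scaling, moved less. Their means were 12.59 and 12.23 on the UNM arrays, 12.60 and 12.47 on the BCP arrays and 12.84 and 12.77 on the TCP arrays. The size of the shift thus depended on the controls chosen. Rises made up 45.6% after a repeated quantile normalization (5521 rose and 6587 fell) and 44.9% after centring on the 75th percentile (5488 rose and 6744 fell). From BCP to TCP the median difference of all probe sets was 0.14 as deposited, 0.34 after centring on the 75th percentile and -1.09 after scaling by the hybridization controls. From UNM to BCP it was 0.06, 0.23 and -0.20, and from UNM to TCP 0.20, 0.56 and -1.30. From BCP to TCP the median of 22 of 36 gene lists turned from a rise to a fall after scaling by the hybridization controls, and falls then outnumbered rises in all 36. From UNM to TCP the median of 11 of 36 lists turned from a fall to a rise after centring on the 75th percentile, and that of 7 from a rise to a fall after scaling by the hybridization controls.

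Of 22 ribosomal protein genes 20 fell and 0 rose. Beside RPL9 and RPS15, RPL5 fell by 6.07 (SE 0.13). The list's median difference was -3.52 with an adjusted p of 1.66e-06 by camera, and adjusted p = 0.630 with an estimated correlation. Of 16 genes of proteasome subunits 13 fell and 0 rose, with OsPAE1 at -3.27 (SE 0.12), OsRPN7 at -3.01 (SE 0.13) and OsPAD1 at -2.70 (SE 0.14). Their median difference was -1.47 with an adjusted p of 0.00149 by camera, against adjusted p = 0.634 with an estimated correlation and 0.0657 after scaling by the hybridization controls, when the median was -2.70 and all 16 fell. Of 17 genes of protein folding in the endoplasmic reticulum 11 fell and 1 rose. The protein disulfide isomerase genes OsPDIL1-1 and OsPDIL2-3 fell, with differences of -6.01 (SE 0.12) and -5.92 (SE 0.19), as did ERDJ3B, a co-chaperone (-5.38, SE 0.14). Their median difference was -3.07 with an adjusted p of 0.00445 by camera, and adjusted p = 0.634 with an estimated correlation. Of 24 heat shock genes 6 fell and 0 rose, or 14 and 0 after scaling by the hybridization controls, among them HSP81-3, HSP81-2 and HSP81-1, of the HSP90 chaperones, at -4.61 (SE 0.14), -4.07 (SE 0.13) and -2.12 (SE 0.13).

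Signs of hybridization moved with these groups, and of the signs of RNA quality that of GAPDH but hardly that of actin. The difference between the 3' and the middle probe set of the control gene GAPDH was 1.75 higher in TCP than in BCP, and that of actin was 0.04 higher. The ribosomal RNA probe sets were 1.49 (25S) and 1.22 (18S) higher in TCP, and the median shift of the 64 reporter probe sets was 0.24.

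Of 29 expansin genes 5 rose and 0 fell as deposited, and 1 rose and 11 fell after scaling by the hybridization controls. EXP32 rose by 3.72 (SE 0.12) from 7.98 ± 0.05 to 11.70 ± 0.09, and EXP26 and EXPB17 by 1.75 (SE 0.14) and 1.25 (SE 0.13), which became 0.52 and 0.02 after that scaling and no longer passed. The list's median difference was 0.36, but -0.87 after that scaling. Its adjusted p was 0.00675 by camera, against adjusted p = 0.630 with an estimated correlation and 0.0617 after that scaling. Of 29 cellulose synthase and related genes 3 rose and 5 fell, or 2 and 19 after that scaling, when their median moved from 0.18 to -1.05, with CSLD5 at 5.74 (SE 0.13), CSLC9 at 5.15 (SE 0.16) and CESA1 at -4.39 (SE 0.13). Of 77 calcium sensors and calcium-dependent kinases 19 rose and 18 fell, or 11 and 44 after that scaling. CPK21 rose by 6.32 (SE 0.13) and CIPK5, of the kinases regulated by calcineurin B-like proteins, by 4.62 (SE 0.16), and CBL3, a calcineurin B-like protein, fell by 4.86 (SE 0.12). Of 22 potassium transporter genes of the HAK family 2 rose and 6 fell, or 2 and 13 after that scaling, when their median moved from 0.16 to -1.07, and beside HAK20 the gene HAK18 rose by 2.77 (SE 0.14).

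Of 12 sugar transporter genes 1 rose and 1 fell, or 1 and 6 after scaling by the hybridization controls, and these were SWEET5, from 6.42 ± 0.30 to 12.70 ± 0.09, and SWEET6A, from 10.43 ± 0.19 to 6.41 ± 0.10. Of 25 genes of sucrose and hexose use 7 fell and 0 rose, or 24 and 0 after that scaling, with the sucrose synthase gene OsSUS4 at -4.03 (SE 0.12). Of 7 starch synthesis genes 2 fell and 0 rose, or 4 and 0 after that scaling. The falls as deposited were SSI, from 11.19 ± 0.03 to 6.67 ± 0.05, and AGPS2, from 11.42 ± 0.05 to 8.55 ± 0.03. GBSS-I was counted by a probe set shared with other transcripts, which did not pass. Other probe sets of GBSS-I had means of 12.52, 11.50 and 12.33 in BCP against 8.71, 8.08 and 9.78 in TCP. The weak ones had means of 3.93 and 5.04 in BCP against 3.52 and 5.04 in TCP. Of 20 genes of glycolysis and fermentation 1 rose and 3 fell, or 1 and 17 after that scaling, and the rise as deposited was that of FBA2 (2.31, SE 0.13). Of 21 cell cycle genes 6 rose and 4 fell, or 2 and 10 after scaling by the hybridization controls, with CYCD5-2 at 3.46 (SE 0.14), MCM4 at 2.81 (SE 0.14) and CYCB2 at -2.66 (SE 0.20). Of 30 genes of DNA replication 5 rose and 14 fell, or 1 and 21 after that scaling, with FEN1A at -4.90 (SE 0.31), OsRFC4 at -2.89 (SE 0.12) and PCNA at -2.87 (SE 0.13). Of 32 kinesin genes 3 rose and 13 fell, or 2 and 25 after that scaling, with KIN7J and KIN7K (3.38, SE 0.12) among the rises and KIN14C (-3.62, SE 0.16) among the falls.

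Of 23 genes of small RNA pathways 2 rose and 10 fell, or 0 and 17 after scaling by the hybridization controls, among them the argonaute genes AGO4B (-3.56, SE 0.23) and AGO18 (-3.14, SE 0.18). Of 31 MADS box genes 3 rose and 4 fell, or 1 and 22 after that scaling, with MADS27 at 5.78 (SE 0.12) and MADS56 at -3.38 (SE 0.20). Of the 11 anther-wall markers 1 fell and 0 rose, or 6 and 0 after that scaling, and the fall as deposited was GAMYB, from 8.37 ± 0.17 to 4.49 ± 0.15. Of 9 meiosis genes 1 rose and 1 fell, or 0 and 8 after that scaling, with SPO11-4 at -2.53 (SE 0.17). Of 6 WRKY genes 1 rose and 0 fell, or 0 and 3 after that scaling. Of the 6 genes matched by the vesicle traffic list 2 fell and 0 rose, or 4 and 0 after that scaling, and the falls as deposited were RAB16D (-1.32, SE 0.20) and RAB5A (-1.15, SE 0.12, but -0.95 after centring on the 75th percentile, under the minimum difference). Over the 32 lists that camera did not call in this comparison, adjusted p ran from 0.183 to 0.988.

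**Figure D2:**
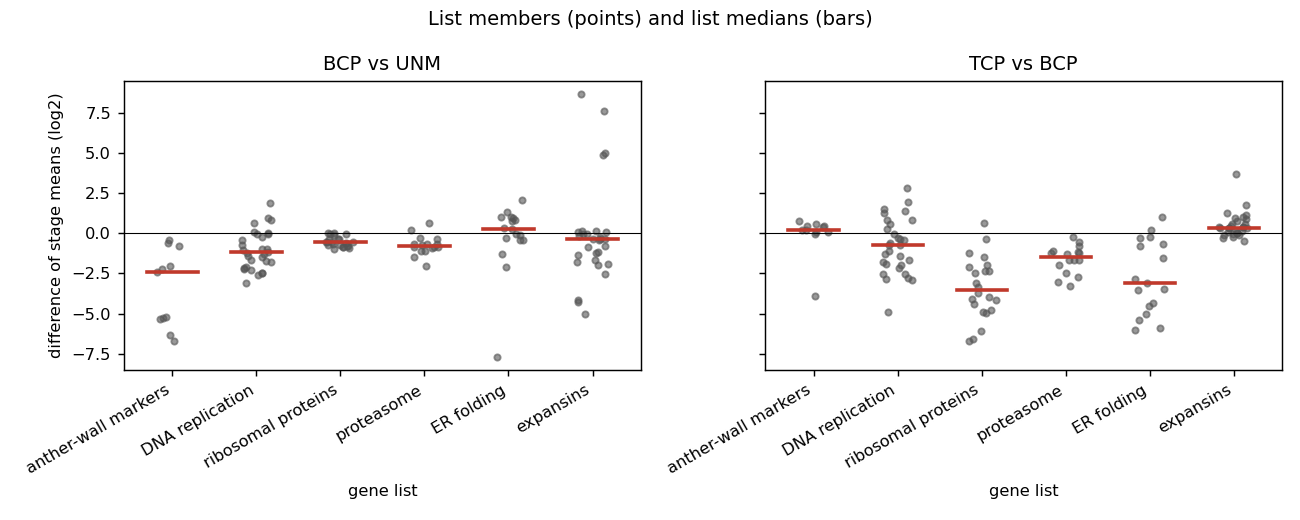
Difference of stage means on the log2 scale (vertical axis) for the members of 6 gene lists (horizontal axis) in BCP compared with UNM and in TCP compared with BCP, with a point per gene and a bar at each list's median. The median of the ribosomal protein genes was -0.57 from UNM to BCP and -3.52 from BCP to TCP, and that of the expansins from BCP to TCP was 0.36 as deposited and -0.87 after scaling by the hybridization controls, when that of the anther-wall markers moved from 0.21 to -1.02.

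**Figure D3:**
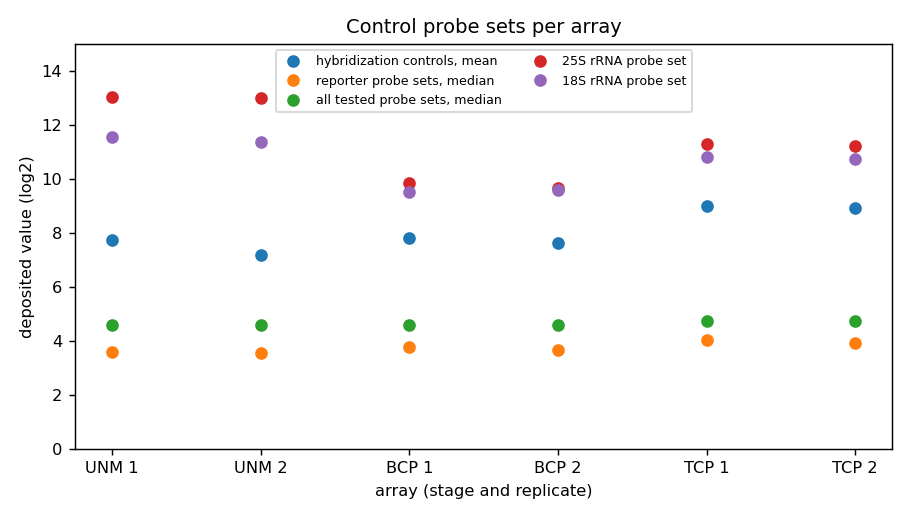
Deposited values on the log2 scale (vertical axis) of control probe sets on each of the 6 arrays (horizontal axis), with a point per array for the mean of 21 hybridization controls, the median of 64 reporter probe sets, the median of all tested probe sets and the 25S and 18S ribosomal RNA probe sets. The hybridization controls lay between 7.18 and 7.81 on the UNM and BCP arrays on average at 7.46 and 7.72, and on the TCP arrays at 8.95 on average.

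The comparison of TCP with UNM spanned the whole series. Of the 8 largest rises among genes with a name 4 were kinases of calcium signalling and 2 were expansins. CIPK5 (gene 4327093) rose from 3.84 ± 0.24 to 13.04 ± 0.08, CIPK30 (gene 4325611) from 3.48 ± 0.20 to 12.49 ± 0.12, and CPK2 (gene 4327560) from 3.38 ± 0.11 to 12.37 ± 0.02. NifU1 (gene 4351651), of a family of scaffolds for iron-sulfur clusters, rose from 3.56 ± 0.36 to 12.91 ± 0.12 by a probe set shared with other transcripts. The gene's other probe set had a difference of 0.84 and did not pass both criteria. PDI (gene 4350002), the protein disulfide isomerase also called OsPDIL1-1, fell from 12.73 ± 0.05 to 4.63 ± 0.06, and BIP4 from 11.51 ± 0.14 to 3.58 ± 0.35.

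By limma with Benjamini-Hochberg adjustment, adjusted p was 5.98e-08 for CIPK5, 9.17e-08 for NifU1 and 5.43e-08 for PDI. The other large rises were EXPB9 (8.80, SE 0.22), CPK22 (8.77, SE 0.18), the thioredoxin gene OsTrx20 (8.70, SE 0.19) and EXP32 (8.70, SE 0.12). The other large falls were RPL9 (-7.60, SE 0.14), 4CLL1, of the 4-coumarate-CoA ligase-like enzymes (-7.45, SE 0.17), RPS15 (-7.44, SE 0.12), the RNA-binding protein gene RBM8 (-7.41, SE 0.20), CAB2R (-7.41, SE 0.13) and EF-1-beta (-7.38, SE 0.20). In total 17129 probe sets changed, of which 6903 rose and 10226 fell, so that rises made up 40.3%. Without a minimum difference 17658 rose and 13323 fell, and rises made up 57.0%. After centring on the 75th percentile 13305 rose and 8607 fell, so that rises made up 60.7%, and after scaling by the hybridization controls 1976 rose and 39685 fell, so that rises made up 4.74%. Changes of more than 4 on the log2 scale were found in 1027 rises and 1898 falls. With 1 probe set per gene, 2575 genes rose and 6744 fell.

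Of 22 ribosomal protein genes 20 fell and 0 rose, with a median difference of -4.19 and an adjusted p of 6.55e-05 by camera, and adjusted p = 0.630 with an estimated correlation. Of 16 genes of proteasome subunits 14 fell and 0 rose, with OsPAE1 at -4.16 (SE 0.12), PAF1 at -3.99 (SE 0.24) and OsRPN7 at -3.86 (SE 0.13). Their median difference was -2.40 with an adjusted p of 0.00352 by camera, against adjusted p = 0.634 with an estimated correlation and 0.0617 after scaling by the hybridization controls, when the median was -3.89 and all 16 fell. Of 17 genes of protein folding in the endoplasmic reticulum 11 fell and 0 rose, with a median difference of -3.51. Of the 11 anther-wall markers 9 fell and 0 rose, with a median difference of -4.69. Camera's adjusted p for these last lists was 0.0676 and 0.0700, and over the 34 lists that it did not call in this comparison the values ran from 0.0676 to 0.998. Beside these groups, the hybridization controls were 1.49 higher in TCP than in UNM, and 20 of the 21 passed both criteria. The difference between the 3' and the middle probe set was 1.39 higher in TCP for GAPDH but moved by -1.19 for actin, and the ribosomal RNA probe sets differed by -1.75 (25S) and -0.68 (18S).

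Of 30 genes of DNA replication 1 rose and 18 fell, or 0 and 26 after scaling by the hybridization controls, with PCNA at -5.99 (SE 0.13) and OsRFC4 at -5.07 (SE 0.12). Of 23 genes of small RNA pathways 1 rose and 13 fell, or 0 and 22 after that scaling, with DCL4, a dicer-like enzyme, at -5.66 (SE 0.14) and AGO17 at -3.58 (SE 0.14). Of 57 auxin genes 5 rose and 27 fell, or 2 and 49 after that scaling, with OsGH3-2 at 5.99 (SE 0.22) and ARF13 at -5.26 (SE 0.20). Of 7 autophagy genes 6 fell and 0 rose, with APG5 at -3.04 (SE 0.21). Of 77 calcium sensors and calcium-dependent kinases 21 rose and 30 fell, with a median difference of -0.21. These were 24 and 27 after centring on the 75th percentile, with a median of 0.16, and 16 and 50 after scaling by the hybridization controls. Of 27 actin regulators 8 rose and 11 fell, or 6 and 16 after scaling by the hybridization controls, when their median moved from 0.03 to -1.46, with ADF-9, also called ADF9, at 8.55 (SE 0.17), ADF1 at 6.47 (SE 0.20) and ADF6 at 6.01 (SE 0.13). Of the 4 genes of the actin list 3 rose and 1 fell, or 2 and 1 after that scaling, with actin-6 at 4.59 (SE 0.14). Of 7 starch synthesis genes 3 rose and 1 fell, or 2 and 4 after scaling by the hybridization controls, with GBSS-I at 7.80 (SE 0.13). The size for GBSS-I depended on the probe set. Its other probe sets had means of 5.52, 4.96 and 4.16 in UNM against 8.71, 8.08 and 9.78 in TCP. The weak ones had means of 3.16 and 4.73 in UNM against 3.52 and 5.04 in TCP. Of 12 sugar transporter genes 1 rose and 5 fell, or 1 and 11 after that scaling, with SWEET5 at 7.75 (SE 0.17) and SWEET11 at -5.58 (SE 0.16). Of 29 expansin genes 4 rose and 9 fell, with a median of -0.17, or 5 and 6 after centring on the 75th percentile, with a median of 0.20, and 4 and 22 after scaling by the hybridization controls.

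Of 21 cell cycle genes 1 rose and 6 fell, or 1 and 18 after scaling by the hybridization controls, with CYCD5-2 at 5.22 (SE 0.14) and MCM2 at -2.78 (SE 0.13). Of 24 heat shock genes 1 rose and 9 fell, or 0 and 22 after that scaling, with HSP81-3 at -5.16 (SE 0.14). Of 31 MADS box genes 4 rose and 14 fell, or 1 and 27 after that scaling, with MADS27 at 5.89 (SE 0.12) and MADS1 at -3.16 (SE 0.24). Of 6 WRKY genes 0 rose and 2 fell, and of the 6 genes matched by the vesicle traffic list 0 rose and 2 fell, with rab25 at -2.90 (SE 0.19), and after that scaling all 6 of each list fell. Of 9 meiosis genes 3 rose and 2 fell, or 0 and 5 after that scaling. Among them PAIR2, of the meiotic chromosome axis, fell, with a difference of -1.30 (SE 0.17) as deposited, but of -0.94 after centring on the 75th percentile, under the minimum difference.

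**Figure D4:**
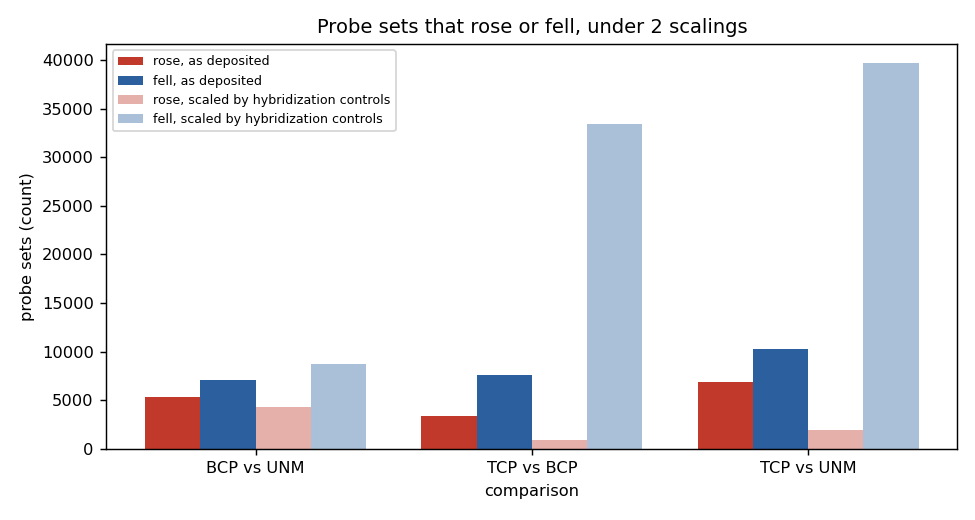
Number of probe sets that rose or fell (vertical axis) in each of the 3 comparisons (horizontal axis), as deposited (solid bars) and after scaling by the hybridization controls (pale bars). From BCP to TCP, 3399 rose and 7593 fell as deposited, against 921 and 33406 after the scaling.

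Across the 3 stages, 20760 of 57194 probe sets (36.3%) changed by limma's moderated F test with a range of the stage means of at least 1. Of these 9260 were highest in UNM, 5279 in BCP and 6221 in TCP. A steady fall from UNM over BCP to TCP was the order of the means in 6195 probe sets, PCNA among them, and a steady rise in 5147, CPK2 among them. BCP had the highest and TCP the lowest mean in 2994 probe sets and BCP the highest and UNM the lowest in 2285, which include GBSS-I. UNM had the highest and BCP the lowest mean in 3065 probe sets, which include JAZ13, and TCP the highest and BCP the lowest in 1074, which include MCM4. These counts depended on the scaling. After scaling by the hybridization controls 33119 of 45322 probe sets were highest in UNM, 10981 in BCP and 1222 in TCP, with a steady fall in 32780 and a steady rise in 873. After centring on the 75th percentile 8023 of 25845 were highest in UNM, 5320 in BCP and 12502 in TCP, with a steady fall in 4737 and a steady rise in 11209.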

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

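Scaling by the hybridization controls was chosen after seeing the data, and the other alternatives were planned. The numbers of changed probe sets are given in the order BCP against UNM, TCP against BCP, TCP against UNM and across the 3 stages. They were 12330, 10992, 17129 and 20760 as reported, and stayed within 1.5 times these values after quantile normalisation again, centring on the median or the 75th percentile, leaving out dim or shared probe sets, an intensity trend, a robust prior and, for the pairs of stages, a fit of only the 2 stages compared. With 1 probe set per gene they were 7576, 6650, 9320 and 11354, where only 17905 genes were tested. Without a minimum difference they were 19620, 21767, 30981 and 31757, and with a minimum of 2 on the log2 scale 5643, 5018, 8827 and 11086, which follows from the criterion. Scaling by the hybridization controls gave 34327 for TCP against BCP, 41661 for TCP against UNM and 45322 across the stages, because it lowers all TCP values, but 13008 for BCP against UNM. Leaving out each array in turn gave 12160 to 12353, 10946 to 11589, 16682 to 17756 and 20159 to 21389, where the lone array left in a stage is assumed to vary like the others. A replicate block in the same fit gave 12329, 10995, 17130 and 20761. The replicate numbers do not pair the samples: correlations of the replicates' deviations were -0.05, -0.07 and 0.01 between stages. The block changed no call of a named gene or of a list called as reported.

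Of 370 results for named genes, 340 were calls. After scaling by the hybridization controls 13 that were calls as deposited or after the scaling changed sign, 9 others lost a call and 12 others gained one. Sign changes of results that were calls in neither setting were not counted. From BCP to TCP the differences became -0.032 for wrky38, -0.059 for SPO11-2, -0.12 for PETE, -0.18 for APG12, -1.04 for AP25, -1.15 for CP1, -1.13 for CYP703A3, -1.02 for C4, -1.23 for PAIR1 and -1.09 for MEL1, and from UNM to TCP -1.13 for PTC1, -1.26 for PAIR1 and -0.33 for DMC1. These differences follow from a shift of 1.23 and 1.49 applied to every gene. The calls of wrky38, SPO11-2, PETE, APG12 and DMC1 ended. The other results named here were calls only after the scaling, so that no call turned into an opposite call. Centring on the 75th percentile took 8 calls and gave 2, and an intensity trend 0 of either. Leaving out a UNM, BCP or TCP array took between 2 and 8 calls, among them those of PETE from BCP to TCP (0.59 without BCP replicate 1) and LHCP from UNM to BCP (-1.12 without UNM replicate 1), and gave at most 2. Of 10 list calls, 0 held with an estimated correlation, 5 held after scaling by the hybridization controls, and 9 without UNM replicate 2, when DNA replication had an adjusted p of 0.0565. In the other alternatives run for lists 10 of 10 held. Among these, fry called 31, 25 and 31 of 36 lists in the 3 comparisons, so that holding with fry tells little about these 10. The 5 calls that ended with the hybridization controls were those of DNA replication and autophagy from UNM to BCP, expansins and the proteasome from BCP to TCP and the proteasome from UNM to TCP. The gap between the list's median and that of all other genes was the same before and after, at -1.05, -1.92, 0.42, -1.41 and -2.05, as was the SD among members, at 1.21, 0.75, 0.80, 0.87 and 1.14. The median residual SD of the fit rose from 0.16 to 0.29. The means of the hybridization controls were 7.74 and 7.18 on the UNM arrays and 7.81 and 7.64 on the BCP arrays. They were 8.998 and 8.911 on the TCP arrays. The scaling thus shifted replicates of a stage by different amounts in every probe set, which adds to the residual SD. Because the scaling added a constant per array, nothing else in it could change the residuals. The equal gaps and SDs among members likewise follow by construction. Whether the larger residual SD accounts for the ended calls was not tested. Signal over background limits falls to the reporter level and rises from it alike, since a level near that of the reporters cannot be told from background, and between 27.8% and 42.3% of probe sets lay above the reporters' 95th percentile on an array.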

Other observations

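The tests of explanations below were all chosen after the patterns had been seen. Several families of signalling and regulatory genes, by lists added after the annotation was seen, changed in both directions as deposited, but from BCP to TCP falls outnumbered rises in each of these lists after scaling by the hybridization controls. Of 55 PP2C genes, protein phosphatases that include negative regulators of abscisic acid signalling, 17 rose and 19 fell from UNM to BCP, 12 rose and 14 fell from BCP to TCP (3 and 27 after scaling by the hybridization controls), and 10 rose and 15 fell from UNM to TCP (16 and 15 after centring on the 75th percentile, 7 and 38 after scaling by the hybridization controls). OsPP2C59 rose from 5.35 ± 0.15 in UNM to 11.01 ± 0.04 in BCP, OsPP2C78 rose from 4.71 ± 0.31 in BCP to 10.92 ± 0.03 in TCP, and OsPP2C39 rose from 7.48 ± 0.04 to 11.16 ± 0.03 and then fell to 5.68 ± 0.31 (n = 2 arrays each). Of 28 cytokinin genes 5 rose and 7 fell from UNM to BCP, and 2 rose and 4 fell from BCP to TCP (0 and 17 after that scaling, with a median of -1.22). The cytokinin-activating enzyme gene LOGL7 was higher in BCP than in UNM by 3.27 (SE 0.13) and LOGL1 lower in TCP than in BCP, with a difference of -3.38 (SE 0.12). Of 22 HAK potassium transporter genes 6 rose and 6 fell from UNM to BCP, with HAK3 at 6.13 (SE 0.20) and HAK23 at 4.69 (SE 0.17).

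Of 33 homeobox genes 2 rose and 10 fell from UNM to BCP, with HOX4 at -5.00 (SE 0.16) and OsWOX6 at -3.76 (SE 0.22), and 1 rose and 4 fell from BCP to TCP (0 and 21 after scaling by the hybridization controls, when the median moved from 0.11 to -1.12). Of 26 NAC and bZIP genes 4 rose and 8 fell from UNM to BCP, and 3 rose and 4 fell from BCP to TCP (1 and 13 after that scaling, when the median moved from 0.20 to -1.03), with NAC067 at -3.44 (SE 0.17). Of 20 heat stress transcription factor genes 1 rose and 3 fell, and then 0 rose and 5 fell (0 and 13 after that scaling), with HSFA2D at -3.11 (SE 0.12) and HSF1 at -3.09 (SE 0.14). Of 8 seed storage protein genes 1 rose and 1 fell, and then 1 rose and 0 fell (1 and 7 after scaling by the hybridization controls). The rise was that of the glutelin gene GLUA-2, from 5.84 ± 0.06 in UNM over 8.24 ± 0.03 in BCP to 11.56 ± 0.04 in TCP. These lists were not called by camera. In other control probe sets, those for the rice blast fungus genes ef1a and gapdh were higher in TCP than in UNM by 2.07 (SE 0.26) and 1.63 (SE 0.18). On the UNM arrays ef1a was at 4.24 and 4.21 and gapdh at 4.92 and 4.67, under the reporters' 95th percentile. On the TCP arrays they were at 6.32 and 6.28 and at 6.46 and 6.39, where that percentile was 5.72 and 5.84. From UNM to BCP ef1a already differed by 1.38 (SE 0.26). Whether these signals come from fungal RNA was not tested.

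From UNM to TCP, 3927 of 34663 unnamed probe sets rose (11.3%) and 2587 fell (7.46%), whereas of 22436 probe sets with 1 gene 2967 rose (13.2%) and 7608 fell (33.9%). This pattern depended on the scaling: of the unnamed probe sets 675 rose and 22336 fell after scaling by the hybridization controls, and 8973 rose and 2090 fell after centring on the 75th percentile. A first form of it, that unnamed probe sets rise more often, is left open, since their share of rises differed by -1.90 points as deposited and by -2.71 without shared probe sets, and was 1.95% against 5.79% after scaling by the hybridization controls, but 25.9% against 19.2% after that centring. Weak signals lifted on the TCP arrays may account for part of the rises as deposited, because 33.0% of these lay under the reporters' 95th percentile in TCP, between the limits of 25% and 50% set for the test, against 9.10% of the rises with 1 gene, so that this stays open. Unnamed probe sets also had lower signals, with a median level of 4.19 in BCP and 4.42 in TCP, against 5.69 and 5.31 for those with 1 gene. Background limits falls, so the shares that fell were not compared at like levels. No biological explanation was tested.

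Marker genes of the anther wall were high in UNM and near the reporter level in BCP and TCP, except GAMYB in BCP. RNA of anther-wall cells in the UNM samples cannot be told apart from transcription of these genes in the microspores themselves, a difference between the stages, because either would give what was seen. In UNM 9 of 11 markers (81.8%) lay above the reporters' 95th percentile of 5.11, against 1 in BCP and 0 in TCP. C6, C4 and AP25 had the highest signals at 10.82, 10.65 and 10.26, but OsRAFTIN1 and PTC1 lay below that percentile at 4.26 and 4.46. Signals of different probe sets do not rank transcript levels. None of the 11 is in another list, and the labels name no step that would remove such cells. Green tissue in the samples stays open, since 4 of 12 photosynthesis genes fell from UNM to BCP, fewer than this explanation asked for.

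Genes of ribosomal proteins fell from BCP to TCP. Probes shared by several transcripts are argued against as the cause, because 94.1% of the 17 genes measured without such probe sets fell. A scaling shift equal for all probe sets of an array is also argued against as the whole cause. The list's median lay 3.45 below that of the 2457 genes with a name (a difference of -3.45, where that median was -0.07). Scaling effects that depend on the signal level were not tested and stay open. The gap cannot decide on them, because the genes with a name were not matched to the list for level and background limits falls. Lower RNA quality in TCP cannot be told apart from the stage, because the 3' to middle difference was higher by 1.75 for GAPDH but by 0.0366 for actin. A biological change between the stages may also account for the fall and was not tested separately.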
